A study of Mus musculus with 8 samples.

How the data were processed

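Ribosome-associated RNA was sequenced from mouse liver. Per the labels, RNA was purified with RNeasy columns, ribosomal RNA was depleted (FastSelect), and libraries were made from 100 ng of total RNA with a KAPA RNA HyperPrep stranded kit. The submitters' processing notes name STAR 2.7.3a, Cufflinks and the mouse genome build mm10. The authors deposited a table of STAR counts per gene symbol for 24982 genes, used here without change as counts, and a Cufflinks table for 24917 genes whose values are FPKM by the authors (fragments per kilobase of transcript, scaled by mapped fragments), although its name calls it counts. The counts are whole numbers whose sums differ between libraries, and 65 genes are in the count table alone. Neither the counting strand nor the annotation release is stated, so antisense reads may be included. FPKM of 0 stood beside more than 1000 counts for 1 to 8 genes per library, and the FPKM table was used only as an alternative. Of the gene symbols, 24853 (99.5%) were found in reference lists of mouse gene symbols. Gene positions came from the GENCODE vM21 reference annotation (mm10).

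The labels give 2 libraries per group without saying that they come from separate animals. If they do not, the p-values measure only the spread between these samples. No replicate numbers link libraries across groups.

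The contrasts, gene lists, tests of the contrasts and lists, thresholds, the rule for naming genes and all but 3 of the 24 alternatives were chosen before the data were examined. The other 3, chosen after the data were seen, are fits without ribosomal RNA genes, with the RN45S share as a covariate, and without the female and the lowest-count library, and ranges over alternatives include them. Genes were kept by the filterByExpr function of edgeR, which left 14147. Scaling used trimmed means of M-values (TMM; factors 0.460 to 1.41), and the effective library sizes were 4.51 M to 47.2 M counts. CPM are counts scaled to an equal TMM-effective library size (per M). A quasi-likelihood negative binomial model with robust dispersion (edgeR 4.0.16 in R 4.3.3) was fitted to 4 group means, leaving 4 residual degrees of freedom, with a common biological coefficient of variation of 23.0%. The 7 contrasts were BDL in each genotype, genotype in each condition, their interaction, and each effect averaged over the other. Tests were two-sided F tests, p-values were adjusted by Benjamini-Hochberg over all genes of a contrast, and a call is an adjusted p under 0.05. The SE of a log2 fold change is its absolute value divided by the square root of F. Libraries of a group correlated with r of 0.961 to 0.988 on log2 CPM, their counts differed by more than counting error (chi-squared per degree of freedom 48.1 to 156), and the first axes of a multidimensional scaling held 57.3% and 14.5% of the variance.

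A set of 26 gene lists was fixed: heme, iron and NRF2, Notch pathway, Kupffer cell, monocyte-derived, lipid-associated and scar macrophage, neutrophil, dendritic cell and MHC class II, inflammatory mediators, repair and regulatory mediators, interferon response, fibrosis and extracellular matrix, stellate cell and fibroblast, hepatocyte, cholangiocyte (bile duct cell), sinusoidal endothelial, T and NK cell, B and plasma cell, erythroid, bile acid synthesis and transport, acute phase, cell cycle, lysosome and phagocytosis, oxidative phosphorylation, ribosomal protein, unfolded protein and stress, and mitochondrially encoded RNA. Lists with at least 5 tested genes, 24 of them, were tested with camera (limma 3.58.1) at its preset correlation between genes of 0.01, which asks whether a list moves against all other genes, with p-values adjusted over the lists of a contrast. Camera with a correlation estimated per list, and fry, were alternatives. Members of a list were also counted with p-values adjusted over the list alone.

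Genes are named by a rule. Hmox1, Lnx1, Notch1, Lyz2 (the Cre locus) and Rpl22 (the RiboTag locus) are named in each contrast. In each contrast the 10 largest positive and 10 largest negative log2 fold changes were taken among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1 over the 8 libraries and CPM that do not overlap between the 2 groups, leaving out predicted genes named Gm or ending in Rik, clone names (AC, AL or BC with a number) and immunoglobulin and T cell receptor segments. Where fewer pass, fewer are named, and where none pass, the 5 with the smallest p are named as not passing. For each list, up to 4 members with the smallest adjusted p are named. Of these, the text gives mainly those whose call held without each library. Where a group had 0 counts, a fold is a bound from a floor of 3 counts over the group, and such floors cover counting error only. Genes that share reads, such as the Mup family and the zinc-finger and predicted genes of chromosome 2, have uncertain single values.

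Alternatives were DESeq2 1.42.0, limma on log2 FPKM (pseudocounts 1 and 0.1, mean FPKM of at least 1, or no filter), other scalings and filters (a mean of at least 50 counts, or none), an adjusted p of 0.1, a test against a fold of 1.5, a fit to only the 4 libraries compared, and fits without each library in turn. In the last, the group left with 1 library is assumed to vary like the others. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 prepared tables and drew plots. The pipeline was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. In 4 runs it recovered 20%, 17%, 19% and 20% of the 2-fold and 87%, 90%, 96% and 91% of the 4-fold changes, with 14, 8, 14 and 15 false calls among 13908, 13975, 13917 and 13910 genes. Changes of about 2-fold were thus mostly missed. Of 200 random lists of 25 simulated genes, 6 had a camera p under 0.05. The simulated genes varied independently, so that count does not cover lists whose members vary together.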

Results

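Ribosome-associated RNA pulled down from mouse liver was sequenced in 8 libraries, whose cell type the labels give as myeloid cells. The mice carried the RiboTag allele, with which Cre adds a hemagglutinin tag to a ribosomal protein, so that tagged ribosomes and the RNA on them can be pulled out of whole liver. Cre was expressed from the LysM (Lyz2) locus, which is active in macrophages, monocytes and neutrophils. The libraries fall into 4 groups of 2. LysM-Cre:Ribotag mice, called wild type here, were sampled as controls and 17 days after bile duct ligation (BDL), an operation that blocks bile flow and leads to cholestasis, bile duct growth and fibrosis. LysM-Cre:Hmoxflfl:Ribotag mice, labelled as carrying a myeloid deletion of Hmox1, were sampled in the same pair of conditions. Hmox1 encodes heme oxygenase-1 (HO-1), the inducible enzyme that breaks down heme. The series title puts the question as what myeloid HO-1 does in liver injury and fibrosis, with LNX1, an E3 ubiquitin ligase that targets the Notch inhibitor Numb, and the receptor Notch1 named as its path. Hmox1 RNA was higher, not lower, in the libraries labelled deleted, so these are called "the libraries labelled HO-1 deleted" throughout.

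Total counts per library ran from 9.81 to 40.9 M. RN45S, the ribosomal RNA precursor, took 10.3% to 66.8% of them, with group means of 14.0 ± 5.23% in wild-type controls, 28.0 ± 12.9% in wild type after BDL, 39.1 ± 23.3% in controls labelled HO-1 deleted and 52.7 ± 19.96% in BDL labelled HO-1 deleted (mean ± SD, n = 2 each). The counts left for all other genes were 20.9 M and 19.5 M in wild-type controls, 20.99 M and 10.5 M in wild type after BDL, 15.0 M and 31.6 M in controls labelled HO-1 deleted, and 15.3 M and 3.25 M in BDL labelled HO-1 deleted. Between 11021 and 14115 genes had at least 10 counts. Wild-type BDL replicate 1 came from a female (Xist 667 CPM, that is counts scaled by library size, and Ddx3y 0), and the other 7 libraries came from males. Hepatocyte transcripts stayed abundant in every library: the 31 hepatocyte genes in the count table, such as the albumin gene Alb, held 10.4% to 16.0% of counts other than RN45S, against 0.0807% to 0.222% for the Kupffer cell list and 0.631% to 1.77% for the monocyte list. The monocyte list includes Hp, also in the acute-phase list, and Fn1, also in the matrix list, so its share is not that of monocytes alone. Libraries without Cre and input RNA were not analysed here, so the share that came from untagged cells was not measured.

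**Figure D1:**
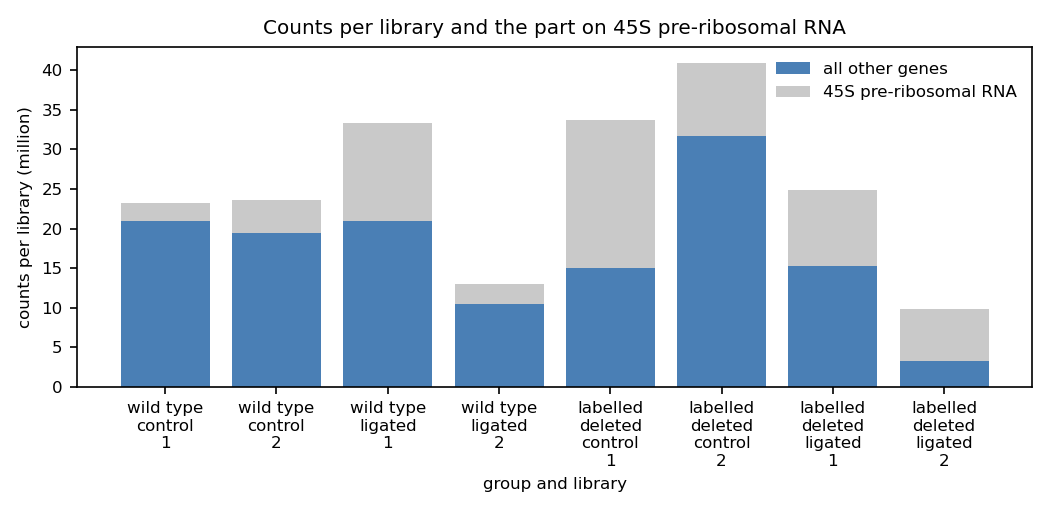
Counts per library in M (bars from 0), with the part assigned to the ribosomal RNA precursor RN45S in grey and all other genes in color, for the 8 libraries in 4 groups. The part other than RN45S ran from 3.25 M (BDL labelled HO-1 deleted, replicate 2) to 31.6 M (control labelled HO-1 deleted, replicate 2).

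In wild-type mice, BDL raised genes of matrix deposition, bile duct cells, monocytes and inflammation, and lowered genes of hepatocyte metabolism. The comparison describes what 17 days of cholestasis does to the RNA captured when HO-1 is present. Lcn2, a neutrophil and acute-phase iron carrier, went from 5.1 ± 0.0632 to 406 ± 79.2 CPM (log2 fold change 6.31 ± 0.55, adjusted p = 8.16e-05), and Rasal1, a Ras GTPase activator, from 0.256 ± 0.274 to 16.3 ± 4.06 CPM (5.98 ± 0.52, adjusted p = 8.16e-05). Slco1a1, which takes organic anions and bile acids into hepatocytes, fell from 262 ± 46.1 to 0.981 ± 0.312 CPM (-8.10 ± 0.39, adjusted p = 8.64e-07), and the sulfotransferase Sult2a8 fell from 246 ± 11.9 to 1.12 ± 0.185 CPM (-7.79 ± 0.36, adjusted p = 8.64e-07). Hmox1 (chromosome 8, 75093621 to 75100589, build mm10) rose from 6.84 ± 0.879 to 25 ± 1.47 CPM (1.87 ± 0.24, adjusted p = 0.000577). Values are mean ± SD of 2 libraries for CPM and estimate ± SE for log2 fold changes, here and below, and the median of a list is that of its genes' log2 fold changes. Unless an overlap is stated, both libraries of a group lay on the same side of both libraries of the other for each gene given as risen or fallen in a comparison of 2 groups.

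Of 31 measured genes of fibrosis and extracellular matrix, 25 rose and 0 fell (27 and 0 adjusted over the list alone). They include the collagen gene Col1a1 (4.41 ± 0.48), the matrix glycoprotein genes Tnc (2.92 ± 0.32) and Fbn1 (2.35 ± 0.27), and Lox, which crosslinks collagen (4.02 ± 0.46; adjusted p 0.000286 to 0.000314). The list was higher as a set. The matrix list had a median of 1.68, with adjusted p = 4.58e-19 by camera and adjusted p = 0.214 with an estimated correlation. Its share of counts other than RN45S was 0.529 ± 0.0075% in controls and 0.969 ± 0.0311% after BDL. Among 18 genes of stellate cells and fibroblasts, 5 rose and 2 fell (6 and 2 adjusted over the list alone), with Col3a1 (2.76 ± 0.43) and the growth factor receptor gene Pdgfra (1.33 ± 0.25) among those that rose. The list was called higher (median 0.74, adjusted p = 0.0192 by camera, adjusted p = 0.45 with an estimated correlation). The call was lost without wild-type control replicate 2 (median 0.85) or without the female library, wild-type BDL replicate 1 (median 0.095). Of 18 bile duct cell genes, 13 rose and 0 fell (14 and 0 adjusted over the list alone), including the RNA-binding protein gene Bicc1 (2.41 ± 0.32), the adhesion gene Epcam (2.80 ± 0.40) and the chloride channel gene Cftr (4.38 ± 0.62). The cholangiocyte list had a median of 2.46, with adjusted p = 3.00e-10 by camera and adjusted p = 0.126 with an estimated correlation. Of 22 sinusoidal endothelial genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone). The endothelial list had a median of -0.09, with adjusted p = 0.626 by camera and adjusted p = 0.874 with an estimated correlation.

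Monocyte and macrophage genes rose as well. Of 19 genes of monocyte-derived cells, 11 rose and 1 fell (14 and 1 adjusted over the list alone), among them the chemokine receptor genes Cx3cr1 (4.13 ± 0.40) and Ccr2 (2.92 ± 0.34) and the integrin gene Itgam (2.77 ± 0.34; adjusted p 0.000138 to 0.000415). The monocyte list had a median of 2.38, with adjusted p = 1.40e-09 by camera and adjusted p = 0.126 with an estimated correlation. Of 20 genes of lipid-associated and scar macrophages, 11 rose and 0 fell (12 and 0 adjusted over the list alone): the lipid receptor gene Trem2 rose by 3.51 ± 0.45, Gpnmb by 4.06 ± 0.52 and Lgals3, which encodes galectin-3, by 2.92 ± 0.41. The lipid-associated macrophage list had a median of 1.94, with adjusted p = 7.61e-09 by camera and adjusted p = 0.293 with an estimated correlation. Its share of counts other than RN45S was 1.38 ± 0.181% in controls and 1.46 ± 0.609% after BDL, with wild-type BDL replicate 2, at 1.03%, below both controls. Of 26 Kupffer cell genes, 7 rose and 0 fell (9 and 1 adjusted over the list alone), including the scavenger receptor gene Marco (2.43 ± 0.32). The Kupffer cell list had a median of 0.73, with adjusted p = 0.000776 by camera and adjusted p = 0.404 with an estimated correlation. Of 12 neutrophil genes, 7 rose and 0 fell (11 and 0 adjusted over the list alone), including the granulocyte growth factor receptor gene Csf3r (1.79 ± 0.28) and the gelatinase gene Mmp9 (2.71 ± 0.43). The neutrophil list had a median of 2.74, with adjusted p = 4.73e-08 by camera and adjusted p = 0.126 with an estimated correlation. In the dendritic cell and MHC class II list, 3 of 15 rose and 0 fell (4 and 0 adjusted over the list alone; median 1.30, adjusted p = 0.00751 by camera, adjusted p = 0.441 with an estimated correlation), and its call ended without wild-type BDL replicate 1 (adjusted p = 0.145). Of 29 lysosome and phagocytosis genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone), with the engulfment receptor gene Axl at 1.38 ± 0.26. The lysosome list had a median of 0.56, with adjusted p = 0.00152 by camera and adjusted p = 0.535 with an estimated correlation. For T and NK cells, 0 rose and 0 fell (0 and 0 adjusted over the list alone) of 6 (median 0.20, mean -0.01 and a downward camera direction, adjusted p = 0.797). For B and plasma cells, 1 rose and 1 fell (1 and 1 adjusted over the list alone) of 11. The B and plasma cell list had a median of -0.40, with adjusted p = 0.214 by camera and adjusted p = 0.508 with an estimated correlation.

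Inflammatory mediators rose: of 16, 10 rose and 0 fell (11 and 0 adjusted over the list alone), among them the monocyte chemokine gene Ccl2 (4.18 ± 0.55), the inflammasome gene Nlrp3 (1.63 ± 0.28) and Tnfaip3, a brake on NF-kB (2.97 ± 0.45). The inflammatory list had a median of 2.09, with adjusted p = 7.04e-08 by camera and adjusted p = 0.133 with an estimated correlation. Of 16 repair and regulatory mediators, 7 rose and 1 fell (8 and 1 adjusted over the list alone), including the interleukin-1 receptor antagonist gene Il1rn (3.21 ± 0.43), the bridging ligand gene Gas6 (2.08 ± 0.28) and the growth factor gene Pdgfb (2.61 ± 0.37). The repair list had a median of 0.94, with adjusted p = 0.00106 by camera and adjusted p = 0.126 with an estimated correlation. The share of counts other than RN45S held by the repair list went the other way, from 0.247 ± 0.00105% to 0.204 ± 0.0204%. That list includes Arg1, which is also in the hepatocyte list. Heme, iron and NRF2 genes rose in part: of 29, 9 rose and 0 fell (10 and 1 adjusted over the list alone), including Hamp, which encodes the iron hormone hepcidin (2.11 ± 0.28), the transcription factor gene Nfe2l2 (1.37 ± 0.22) and G6pdx (1.51 ± 0.26). The heme and iron list had a median of 0.52, with adjusted p = 0.00145 by camera and adjusted p = 0.376 with an estimated correlation. Of 32 Notch pathway genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone), with the target gene Hes1 at 2.08 ± 0.38, and the list was not called. The Notch list had a median of 0.34, with adjusted p = 0.214 by camera and adjusted p = 0.404 with an estimated correlation. Notch1 itself (chromosome 2, 26457903 to 26516663) was at 48.7 ± 12.1 CPM in controls and 71.7 ± 4.84 CPM after BDL (0.56 ± 0.24, adjusted p = 0.138, not called), and Lnx1 at 10.03 ± 0.685 and 13.2 ± 7.15 CPM (0.38 ± 0.41, adjusted p = 0.562, not called). Of 31 cell cycle genes, 19 rose and 0 fell (25 and 0 adjusted over the list alone), including the spindle gene Tpx2 (2.96 ± 0.44), Top2a (2.39 ± 0.38) and the replication gene Mcm2 (1.76 ± 0.34). The cell cycle list had a median of 1.53, with adjusted p = 1.40e-09 by camera and adjusted p = 0.191 with an estimated correlation. Acute-phase genes were higher as a list. Of 21, 8 rose and 1 fell (11 and 1 adjusted over the list alone): Orm3 rose by 3.47 ± 0.29, while Saa4 was lower (-2.18 ± 0.27). The acute phase list had a median of 1.05, with adjusted p = 2.42e-07 by camera and adjusted p = 0.245 with an estimated correlation.

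Of 30 hepatocyte genes, 0 rose and 13 fell (0 and 14 adjusted over the list alone). The drug-metabolizing gene Cyp2c29 (-2.38 ± 0.32), the gluconeogenic gene G6pc (-3.05 ± 0.43) and the protease inhibitor genes Serpina3k (-3.07 ± 0.51) and Serpina1c (-2.45 ± 0.41) were among those that fell. The hepatocyte list had a median of -0.95, with adjusted p = 3.52e-08 by camera and adjusted p = 0.376 with an estimated correlation. The share of counts other than RN45S held by the list was 14.5 ± 0.419% in controls and 13.7 ± 1.81% after BDL, so it moved by less than the spread between libraries. Of 20 genes of bile acid synthesis and transport, 2 rose and 12 fell (3 and 12 adjusted over the list alone): the synthesis gene Cyp7b1 was lower (-4.85 ± 0.65) and the basolateral exporter gene Abcc4 was higher (1.87 ± 0.29). The bile acid list had a median of -1.07, with adjusted p = 9.37e-06 by camera and adjusted p = 0.133 with an estimated correlation. Of 30 genes of oxidative phosphorylation, 0 rose and 15 fell (0 and 19 adjusted over the list alone), and the list was lower. The oxidative phosphorylation list had a median of -0.79, with adjusted p = 7.61e-09 by camera and adjusted p = 0.376 with an estimated correlation. Of 24 interferon response genes, 0 rose and 5 fell (0 and 11 adjusted over the list alone), also lower as a list. The interferon list had a median of -0.76, with adjusted p = 0.00136 by camera and adjusted p = 0.45 with an estimated correlation. The members of these lists with small p, Uqcrc1 (0.00791), Ndufv1 (0.00775), Rsad2 (0.00687) and Ifit1 (0.00791), lost their calls without wild-type control replicate 1 (adjusted p = 0.0847, 0.0726, 0.0900 and 0.104). Of 41 ribosomal protein genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone). The ribosomal protein list had a median of 0.18, with adjusted p = 0.621 by camera and adjusted p = 0.896 with an estimated correlation. It was called lower without the female library, wild-type BDL replicate 1, and higher without wild-type BDL replicate 2. Of 25 genes of protein folding and stress, 7 rose and 2 fell (7 and 2 adjusted over the list alone). The stress list had a median of 0.08, with adjusted p = 0.245 by camera and adjusted p = 0.689 with an estimated correlation. Too few erythroid genes were measured for a list test, and transcripts encoded by mitochondria were absent from the tables.

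By edgeR, 2607 of 14147 genes tested were called (adjusted p under 0.05), 1675 higher and 932 lower, and 2134 of them by more than 2-fold. By camera, 14 of 24 lists were called higher and 4 lower. With an estimated correlation 0 lists held their call, in this and in each of the other 6 comparisons, so every list call in the report rests on the preset correlation of 0.01. A rotation test (fry), which asks whether a set's genes move on balance in 1 direction and does not compare them with other genes, called 12 lists. Without wild-type control replicate 1 the count of called genes was 881 and without replicate 2 it was 1275. The RN45S share was 14.0% in controls and 28.0% after BDL, and with it as a covariate 1477 genes were called (987 higher, 490 lower). With scaling by total counts, which shifted the median of all genes by -0.14, it was 550 (366 higher, 184 lower), and on the deposited FPKM, with a shift of -0.41, it was 387 with the balance turned (113 higher, 274 lower).

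In the libraries labelled HO-1 deleted, the same comparison asks how BDL acts when myeloid HO-1 is meant to be absent. Hmox1 RNA rose here too, from 26.2 ± 5.22 to 83.9 ± 16.4 CPM (1.67 ± 0.24, adjusted p = 0.000634). Gpnmb, a glycoprotein gene of lipid-laden macrophages, went from 0.17 ± 0.119 to 42.3 ± 10.7 CPM (7.74 ± 0.60, adjusted p = 4.57e-05), and Rasal1 from 0.276 ± 0.0884 to 30.9 ± 6.12 CPM (6.72 ± 0.52, adjusted p = 3.97e-05). Fbn2, a microfibril gene, rose from 0.159 ± 0.104 to 15.6 ± 10.7 CPM (6.48 ± 0.62, adjusted p = 0.00011). Sult2a8 fell from 336 ± 81.4 to 0.338 ± 0.149 CPM (adjusted p = 3.92e-07), and the steroid dehydrogenase gene Hsd3b5 fell from 82.1 ± 0.419 to 0.0193 ± 0.0274 CPM (adjusted p = 1.83e-05). Mup1 and Mup12, which encode urinary proteins made by hepatocytes, were at 0 counts after BDL, at least 478-fold and at least 259.5-fold lower against a floor of 3 counts over the group. Reads shared among the Mup genes leave the value of each single Mup gene uncertain.

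Matrix genes rose broadly: of 31, 28 rose and 0 fell (29 and 0 adjusted over the list alone), including Tnc (3.98 ± 0.33), Lox (4.79 ± 0.46), Col1a1 (5.14 ± 0.50) and Fbn1 (2.89 ± 0.27), with adjusted p 4.53e-05 to 9.26e-05. The matrix list had a median of 2.64, with adjusted p = 5.51e-30 by camera and adjusted p = 0.156 with an estimated correlation. Of 18 stellate cell and fibroblast genes, 8 rose and 2 fell (12 and 2 adjusted over the list alone), with Col3a1 at 3.72 ± 0.45 and the receptor genes Pdgfrb at 2.18 ± 0.27 and Pdgfra at 1.97 ± 0.26. The stellate list had a median of 1.16, with adjusted p = 4.76e-05 by camera and adjusted p = 0.253 with an estimated correlation. The stellate list held 0.0632 ± 0.0133% of counts other than RN45S in controls and 0.436 ± 0.0336% after BDL. Of 18 bile duct cell genes, 12 rose and 0 fell (13 and 0 adjusted over the list alone), including the keratin gene Krt7 (4.16 ± 0.54), Bicc1 (2.73 ± 0.33) and Epcam (2.74 ± 0.41). The cholangiocyte list had a median of 2.55, with adjusted p = 5.37e-09 by camera and adjusted p = 0.133 with an estimated correlation. Monocyte genes rose in 13 cases and fell in 0 (13 and 0 adjusted over the list alone) of 19, with the transglutaminase gene F13a1 at 5.43 ± 0.50, Cx3cr1 at 3.99 ± 0.39 and Itgam at 3.52 ± 0.35. The monocyte list had a median of 2.51, with adjusted p = 1.28e-10 by camera and adjusted p = 0.122 with an estimated correlation. Of 20 lipid-associated and scar macrophage genes, 13 rose and 0 fell (15 and 0 adjusted over the list alone), including Cd63 (3.44 ± 0.34), Trem2 (3.53 ± 0.40) and Lgals3 (3.43 ± 0.41). The lipid-associated macrophage list had a median of 2.09, with adjusted p = 1.55e-10 by camera and adjusted p = 0.253 with an estimated correlation. Of 12 neutrophil genes, 8 rose and 0 fell (10 and 1 adjusted over the list alone), among them Lcn2 (5.26 ± 0.52) and the protease gene Prtn3 (4.42 ± 0.55). The neutrophil list had a median of 2.26, with adjusted p = 4.06e-06 by camera and adjusted p = 0.133 with an estimated correlation. Of 15 dendritic cell and MHC class II genes, 9 rose and 0 fell (10 and 0 adjusted over the list alone), with the class II transactivator gene Ciita at 2.62 ± 0.38 and Irf8 at 1.62 ± 0.29. The dendritic cell list had a median of 2.08, with adjusted p = 0.00188 by camera and adjusted p = 0.372 with an estimated correlation.

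Of 41 ribosomal protein genes, 24 rose and 0 fell (28 and 0 adjusted over the list alone), among them Rps20 (1.96 ± 0.25), Rplp0 (1.74 ± 0.31), Rps19 (1.30 ± 0.24) and Rpl13 (1.28 ± 0.22). The ribosomal protein list had a median of 1.07, with adjusted p = 1.03e-07 by camera and adjusted p = 0.389 with an estimated correlation. Rpl22, the RiboTag locus, was at 36 ± 8.34 CPM in controls and 65.2 ± 12.2 CPM after BDL (adjusted p = 0.107, not called). Of 32 Notch pathway genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone), including Numbl (2.27 ± 0.43) and the fringe gene Lfng (1.74 ± 0.33), both modifiers of Notch signaling. The Notch list had a median of 0.36, with adjusted p = 0.0409 by camera and adjusted p = 0.322 with an estimated correlation. That list lost its call without wild-type control replicate 1 (adjusted p = 0.0557), wild-type BDL replicate 1 (0.0601) or 2 (0.0608), control labelled HO-1 deleted replicate 2 (0.0552) or BDL labelled HO-1 deleted replicate 1 (0.200). Notch1 was called higher by a narrow margin (0.72 ± 0.25, adjusted p = 0.0495), with adjusted p from 0.0217 to 0.849 over its 24 alternatives. It lost the call without control labelled HO-1 deleted replicate 1 (0.221) or 2 (0.14), BDL labelled HO-1 deleted replicate 1 (0.236), or wild-type control replicate 1 (0.0583) or 2 (0.0581). Lnx1 was at 1.32 ± 0.43 and 1.38 ± 1.01 CPM (adjusted p = 0.609, not called).

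Hepatocyte genes fell in 7 of 30 cases and rose in 0 (7 and 0 adjusted over the list alone), including Cyp2c29 (-1.95 ± 0.31), Serpina3k (-3.10 ± 0.51) and Cyp2e1 (-2.20 ± 0.39). The hepatocyte list had a median of -0.48, with adjusted p = 0.000222 by camera and adjusted p = 0.508 with an estimated correlation. The list held 14.9 ± 1.57% of counts other than RN45S in controls and 12.9 ± 3.49% after BDL. Of 20 bile acid genes, 2 rose and 8 fell (2 and 9 adjusted over the list alone), with the uptake carrier gene Slco1b2 at -2.34 ± 0.31 and the bile acid receptor gene Nr1h4 at -1.61 ± 0.27. The bile acid list had a median of -0.67, with adjusted p = 0.000465 by camera and adjusted p = 0.204 with an estimated correlation. Acute-phase genes rose as a list. Of 21, 8 rose and 1 fell (9 and 1 adjusted over the list alone): A2m rose by 4.07 ± 0.56 and Saa4 was lower (-2.03 ± 0.27). The acute phase list had a median of 0.84, with adjusted p = 0.000113 by camera and adjusted p = 0.333 with an estimated correlation. For inflammatory mediators, 4 rose and 0 fell (4 and 0 adjusted over the list alone) of 16. The inflammatory list had a median of 0.99, with adjusted p = 0.00188 by camera and adjusted p = 0.253 with an estimated correlation. For repair and regulatory mediators, 9 rose and 1 fell (10 and 1 adjusted over the list alone) of 16. The repair list had a median of 1.13, with adjusted p = 0.000222 by camera and adjusted p = 0.133 with an estimated correlation. Its share of counts other than RN45S was 0.218 ± 0.0253% in controls and 0.228 ± 0.0571% after BDL. For heme, iron and NRF2 genes, 9 rose and 0 fell (10 and 1 adjusted over the list alone) of 29. The heme and iron list had a median of 0.53, with adjusted p = 0.000818 by camera and adjusted p = 0.324 with an estimated correlation. For cell cycle genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone) of 31. The cell cycle list had a median of 0.89, with adjusted p = 0.0015 by camera and adjusted p = 0.372 with an estimated correlation. Kupffer cell genes rose as a list (10 up and 1 down of 26; 12 and 1 adjusted over the list alone). The Kupffer cell list had a median of 0.47, with adjusted p = 0.0141 by camera and adjusted p = 0.534 with an estimated correlation. So did lysosome genes (14 up and 2 down of 29; 16 and 2 adjusted over the list alone). The lysosome list had a median of 0.95, with adjusted p = 0.000386 by camera and adjusted p = 0.534 with an estimated correlation. Both calls ended without BDL labelled HO-1 deleted replicate 2, the library with the fewest counts (adjusted p = 0.199 and 0.105). Oxidative phosphorylation was not called (median -0.37, adjusted p = 0.0729 by camera, adjusted p = 0.694 with an estimated correlation), and neither was the interferon list. The interferon list had a median of -0.18, with adjusted p = 0.214 by camera and adjusted p = 0.699 with an estimated correlation.

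By edgeR, 3895 genes were called, 2140 higher and 1755 lower, and 3026 of them by more than 2-fold. Camera called 16 of 24 lists higher and 2 lower, 0 of which held with an estimated correlation, and fry called 14. Without control labelled HO-1 deleted replicate 1 the count of genes was 1644, and without BDL labelled HO-1 deleted replicate 1 it was 2318. With total counts (median shift -0.28) it was 918 (441 higher, 477 lower), and on the deposited FPKM (shift -0.16) 452 (170 higher, 282 lower). The RN45S share was 39.1% in controls and 52.7% after BDL, and with it as a covariate 3204 genes were called (1799 higher, 1405 lower).

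The responses to BDL in the wild-type libraries and in those labelled HO-1 deleted ran largely in parallel across genes. Fitted log2 fold changes correlated across the 14147 genes with Pearson r = 0.778 and Spearman rho = 0.721. Genes are not independent replicates, so no p-value is attached. Without BDL labelled HO-1 deleted replicate 1, r was 0.518, and without the female library it was 0.655. Of the genes called in wild type, 2547 of 2607 (97.7%) moved in the same direction in the libraries labelled HO-1 deleted. Called higher in both were 1251 genes, where independent lists would share 253, called lower in both were 609, where independent lists would share 116, and 7 were called in opposite directions. Averaged over genotypes (4 libraries against 4), Gpnmb (5.90 ± 0.39), Rasal1 (6.35 ± 0.37) and the antimicrobial oxidase gene Duox2 rose and Slco1a1 was lower (adjusted p 1.07e-08 to 8.13e-05). Hmox1 rose by 1.77 ± 0.17 (adjusted p = 2.04e-05). Notch1 rose by 0.64 ± 0.17 (adjusted p = 0.013), a call lost without wild-type control replicate 1 (adjusted p = 0.0748) or control labelled HO-1 deleted replicate 1 (0.0568). Matrix genes rose in 28 of 31 cases and fell in 0 (30 and 0 adjusted over the list alone). The matrix list had a median of 2.20, with adjusted p = 1.76e-27 by camera and adjusted p = 0.142 with an estimated correlation. Hepatocyte genes rose in 2 and fell in 16 of 30 (2 and 16 adjusted over the list alone). The hepatocyte list had a median of -0.74, with adjusted p = 2.03e-06 by camera and adjusted p = 0.379 with an estimated correlation.

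Averaging called 5539 genes, 3023 higher and 2516 lower, with 15 of 24 lists higher and 4 lower by camera, 0 of them with an estimated correlation, and 16 by fry. Among these the interferon list (median -0.33, adjusted p = 0.0236 by camera, adjusted p = 0.566 with an estimated correlation) lost its call without wild-type control replicate 1 (adjusted p = 0.0754), wild-type BDL replicate 1 (0.0701), control labelled HO-1 deleted replicate 2 (0.0625) or BDL labelled HO-1 deleted replicate 1 (0.0946). With total counts (median shift -0.21) 2008 genes were called (1105 higher, 903 lower), and on the deposited FPKM (shift -0.27) 1152 (337 higher, 815 lower). With the RN45S share as a covariate 3616 were called (2110 higher, 1506 lower).

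**Figure D2:**
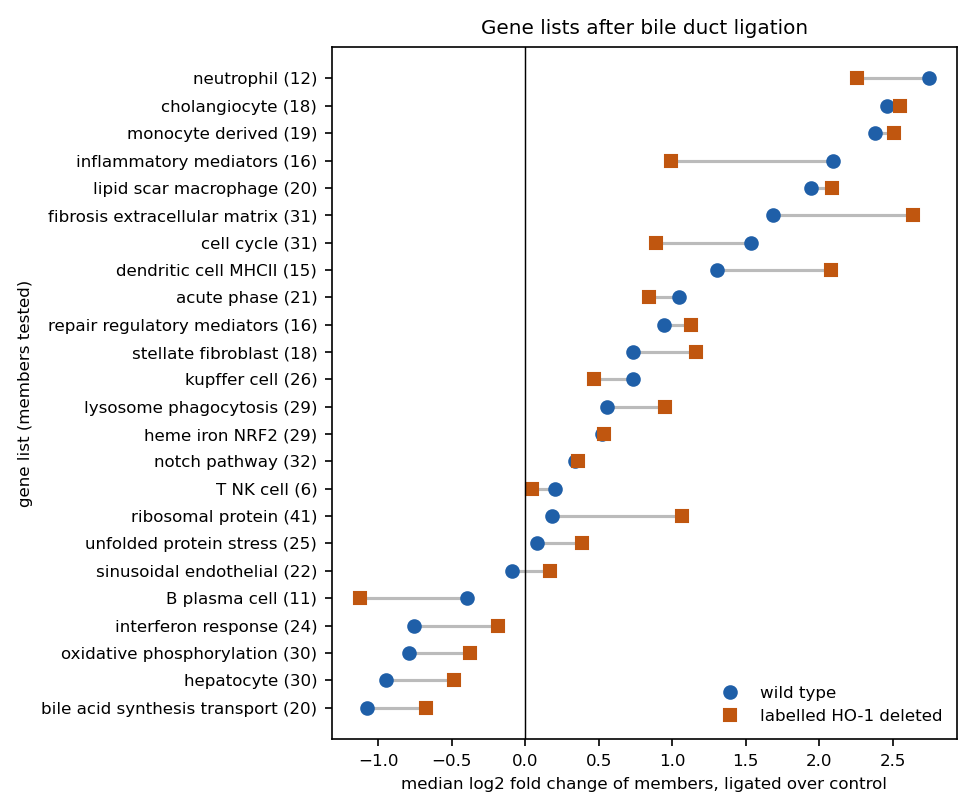
Median log2 fold change after BDL of each gene list (horizontal axis), for wild type (circles) and for the libraries labelled HO-1 deleted (squares), from 4 libraries each. Matrix genes had medians of 1.68 and 2.64, and hepatocyte genes -0.95 and -0.48.

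The genotypes were then compared without BDL, which asks what the myeloid deletion of Hmox1 does in the resting liver. Hmox1 was 6.84 ± 0.879 CPM in wild-type controls and 26.2 ± 5.22 CPM in controls labelled HO-1 deleted. It was higher by 1.94 ± 0.24 (adjusted p = 0.00434). Its call was lost without wild-type control replicate 1 (adjusted p = 0.141) or control labelled HO-1 deleted replicate 2 (0.0544), its log2 fold change ran from 1.01 to 2.10 over 24 alternatives with adjusted p from 8.41e-09 to 0.819, and the value of 1.01 came from the deposited FPKM. Lyz2, the lysozyme gene that carries Cre (chromosome 10, 117277331 to 117282321), was 9.8 ± 2.49 CPM in wild type and 0.17 ± 0.059 CPM in the libraries labelled deleted (-5.72 ± 0.54, adjusted p = 0.00123). Lnx1 (chromosome 5, 74592447 to 74702912) was 10.03 ± 0.685 CPM and 1.32 ± 0.43 CPM (-2.96 ± 0.46, adjusted p = 0.0284), with adjusted p from 1.14e-07 to 0.540 over 24 alternatives. Its call ended without any 1 of the 4 control libraries (adjusted p = 0.144 and 0.0762 without wild-type control replicates 1 and 2, 0.106 and 0.232 without control labelled HO-1 deleted replicates 1 and 2). Notch1 did not differ beyond its error, at 48.7 ± 12.1 and 46.8 ± 2.24 CPM (adjusted p = 0.986), and neither did Rpl22 (adjusted p = 0.697).

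Other genes that were higher in controls labelled HO-1 deleted were Cacna1a, a calcium channel gene, with 2.25 ± 0.779 CPM in wild type and 24.5 ± 2.24 CPM (3.44 ± 0.34, adjusted p = 0.00123), and the imprinted noncoding RNAs Meg3 (2.83 ± 0.27, adjusted p = 0.00123) and Rian (2.73 ± 0.33, adjusted p = 0.00384). Lower were the serine protease inhibitor gene Serpina3c, from 51.4 ± 32 to 0.446 ± 0.0872 CPM (-6.79 ± 0.60, adjusted p = 0.00123), and Dab1, an adaptor gene of reelin signaling, from 5.76 ± 2.64 to 0.372 ± 0.0426 CPM (-3.91 ± 0.38, adjusted p = 0.00123). The zinc-finger gene Zfp971 was 19.7 ± 0.411 CPM in wild type and 0.0318 ± 0.0449 CPM in the libraries labelled deleted (adjusted p = 0.0038), and its reads can be shared with neighboring copies.

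Few list members passed. Of 29 heme, iron and NRF2 genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone), and the list was not called. The heme and iron list had a median of 0.14, with adjusted p = 0.075 by camera and adjusted p = 0.773 with an estimated correlation. The Kupffer cell list was called higher, with 2 of 26 up and 0 down (2 and 0 adjusted over the list alone). The Kupffer cell list had a median of 0.38, with adjusted p = 1.14e-05 by camera and adjusted p = 0.704 with an estimated correlation. So was the acute-phase list, with 1 of 21 up and 0 down (4 and 0 adjusted over the list alone). The acute phase list had a median of 0.70, with adjusted p = 1.26e-08 by camera and adjusted p = 0.704 with an estimated correlation. The inflammatory list was called higher with 0 members up or down (2 and 0 adjusted over the list alone; median 0.52, adjusted p = 0.00145 by camera, adjusted p = 0.704 with an estimated correlation; median 0.45 with Ptgs2, at 0 counts in wild type, at its bound), but not without control labelled HO-1 deleted replicate 2 (adjusted p = 0.259). The oxidative phosphorylation, ribosomal protein and interferon lists were called lower as sets, with 0 of 30, 0 of 41 and 0 of 24 members up or down over all genes or adjusted over the list alone. Oxidative phosphorylation (median -0.41, adjusted p = 2.40e-08 by camera, adjusted p = 0.716 with an estimated correlation), ribosomal proteins (median -0.35, adjusted p = 1.04e-07 by camera, adjusted p = 0.718 with an estimated correlation) and interferon response (median -0.51, adjusted p = 2.40e-08 by camera, adjusted p = 0.704 with an estimated correlation) thus had list calls alone. Sinusoidal endothelial genes were also lower as a list with 0 members called (median -0.19, adjusted p = 0.0108 by camera, adjusted p = 0.762 with an estimated correlation), but not without wild-type control replicate 2 (adjusted p = 0.0556) or control labelled HO-1 deleted replicate 1 (0.113). For monocyte-derived cells, 0 rose and 1 fell (0 and 1 adjusted over the list alone), with a median of 0.14, a mean of -0.09 and a downward camera direction (adjusted p = 0.723). The RN45S share, 14.0% and 39.1% in these groups, moved with genotype, and with it as a covariate 10 genes were called and the interferon list lost its call.

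By edgeR, 27 genes were called, 11 higher and 16 lower, and 968 had an unadjusted p under 0.05. DESeq2 called 100. Camera called 3 lists higher and 4 lower, fry 0 of 24. Without wild-type control replicate 1 the count of genes was 12, and without wild-type BDL replicate 1 or 2 it was 52. Scaling by total counts shifted the median of all genes by -0.53, gave 44 calls (11 higher, 33 lower), turned the Kupffer cell median below 0 and lowered Hmox1 to 1.45 (adjusted p = 0.819).

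**Figure D3:**
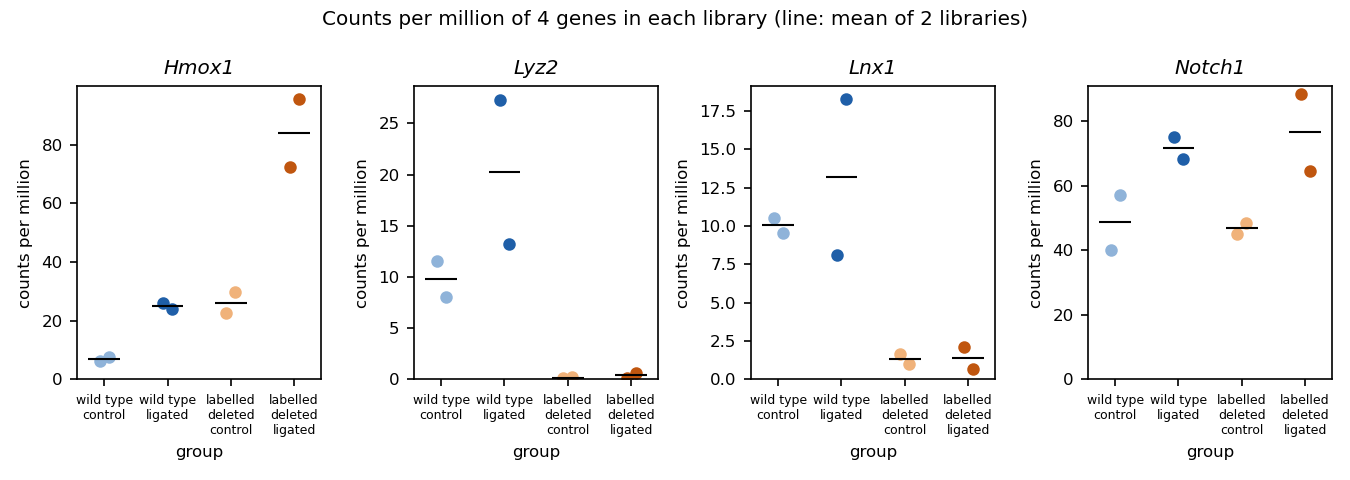
CPM of Hmox1, Lyz2, Lnx1 and Notch1 (vertical axes) in each of the 8 libraries by group, with a line at the mean of the 2 libraries. Hmox1 was 6.22 to 26.0 CPM in wild-type libraries and 22.5 to 95.5 CPM in libraries labelled HO-1 deleted, and Lyz2 8.04 to 27.3 CPM and 0.128 to 0.665 CPM.

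After BDL, the genotype comparison asks what myeloid HO-1 does in the fibrotic liver, the setting of the series title. Hmox1 was 25 ± 1.47 CPM in wild type and 83.9 ± 16.4 CPM in libraries labelled deleted (1.74 ± 0.24, adjusted p = 0.0191). Its adjusted p ran from 2.88e-07 to 0.850 over 24 alternatives, and the call ended without wild-type BDL replicate 2 (adjusted p = 0.0623), BDL labelled HO-1 deleted replicate 1 (0.0642) or replicate 2 (0.141). Cacna1a was 2.48 ± 0.12 CPM and 47.8 ± 20.6 CPM (4.29 ± 0.35, adjusted p = 0.000413). Lower in the libraries labelled deleted were Lyz2 (-6.34 ± 0.61, adjusted p = 0.00156), Dab1 (-4.72 ± 0.39, adjusted p = 0.000413) and the membrane protein gene Tmc5 (-3.66 ± 0.40, adjusted p = 0.00445), calls that ended without BDL labelled HO-1 deleted replicate 1 (adjusted p = 0.144, 0.0642 and 0.142). Lnx1 was 13.2 ± 7.15 CPM and 1.38 ± 1.01 CPM, not called here (adjusted p = 0.0832), with a log2 fold change of -2.96 ± 0.49 and adjusted p from 2.10e-06 to 0.722 over 24 alternatives. Notch1 was 71.7 ± 4.84 and 76.6 ± 16.9 CPM (adjusted p = 0.912), and Rpl22 84.4 ± 36.2 and 65.2 ± 12.2 CPM (adjusted p = 0.716), neither called.

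Matrix genes were higher as a list in BDL labelled HO-1 deleted. Of 31, 0 rose or fell over all genes, whereas 16 rose and 0 fell when adjusted over the list alone, and the collagen VI genes Col6a1 and Col6a2 had log2 fold changes of 1.42 ± 0.32 and 1.47 ± 0.35 (adjusted p 0.187 to 0.207 over all genes). The matrix list had a median of 0.96, with adjusted p = 2.65e-18 by camera and adjusted p = 0.483 with an estimated correlation. The stellate and fibroblast list was also higher with 0 members called either way (0 and 0 adjusted over the list alone). The stellate list had a median of 0.79, with adjusted p = 6.00e-06 by camera and adjusted p = 0.483 with an estimated correlation. Its share of counts other than RN45S was 0.236 ± 0.00773% in wild type and 0.436 ± 0.0336% in the libraries labelled deleted. Both lists held their camera call without each of the 8 libraries in turn. The lipid-associated and scar macrophage list was called higher with 0 members up or down (4 and 0 adjusted over the list alone; median 0.51, adjusted p = 3.86e-07 by camera, adjusted p = 0.483 with an estimated correlation), but not without BDL labelled HO-1 deleted replicate 2 (adjusted p = 0.152). The remaining lists called higher were those of ribosomal proteins (camera adjusted p = 3.86e-07, adjusted p = 0.595 with an estimated correlation), acute phase (0.00017, 0.483), lysosome (0.00308, 0.707), heme and iron (0.00448, 0.533), Kupffer cells (0.00552, 0.609), monocytes (0.00552, 0.483), dendritic cells (0.0282, 0.609), repair mediators (0.0309, 0.483) and neutrophils (0.0458, 0.483), and cell cycle was called lower (0.0309, 0.609). Each of these 10 calls ended without wild-type BDL replicate 2 (adjusted p 0.0690 to 0.710) and without BDL labelled HO-1 deleted replicate 2 (0.0690 to 0.674), the repair list's also without each other library (0.0962 to 0.108), and cell cycle's also without BDL labelled HO-1 deleted replicate 1 (0.136). Of their members, Hmox1 (heme and Kupffer cell lists) was higher and Lyz2 (monocyte list, the Cre locus) was lower, and 0 others were called.

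By edgeR, 9 genes were called, 2 higher and 7 lower, and 1670 had an unadjusted p under 0.05; DESeq2 called 171. The count was 306 without wild-type BDL replicate 1, the female library, 33 without wild-type BDL replicate 2, 1 and 4 without BDL labelled HO-1 deleted replicates 1 and 2, and 264 without the female and the lowest-count library together. Lists called were 13 by camera, 12 higher and 1 lower, and 0 by fry. The RN45S share moved with genotype here too (28.0% and 52.7%), and with it as a covariate 8 genes and 6 lists were called. Total counts shifted the median of all genes by -0.68, gave 95 calls (3 higher, 92 lower), lowered Hmox1 to 0.98 (adjusted p = 0.541) and turned the medians of the heme, Kupffer, lipid-associated, neutrophil, repair, acute-phase, lysosome and ribosomal lists below 0.

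The interaction tests whether the response to BDL differs between the genotypes as labelled. Tmc5, an ion channel-like gene of epithelia, was the gene called: it rose from 0.0796 ± 0.0238 to 15.5 ± 2.92 CPM in wild type and went from 0.393 ± 0.0124 to 1.46 ± 0.753 CPM in the libraries labelled HO-1 deleted (interaction -5.90 ± 0.70, adjusted p = 0.0387). The call ended without wild-type control replicate 1 (adjusted p = 0.193) or 2 (0.231), control labelled HO-1 deleted replicate 1 (0.169) or 2 (0.223), or BDL labelled HO-1 deleted replicate 1 (0.288), and its adjusted p ran from 1.69e-08 to 0.288 over 21 alternatives. For Hmox1 the interaction was -0.20 ± 0.33 (adjusted p = 0.89), for Notch1 0.16 ± 0.35 (0.93), for Lnx1 -0.01 ± 0.82 (adjusted p = 1), for Lyz2 -0.62 ± 0.95 (0.878) and for Rpl22 0.46 ± 0.51 (0.819), so a difference in their response to BDL was not shown. Gpnmb, with the larger rise after BDL in the libraries labelled deleted, had an interaction of 3.67 ± 0.81 (adjusted p = 0.342), not called.

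By list, matrix genes had a more positive response in the libraries labelled HO-1 deleted. The matrix list had a median of 0.87, with adjusted p = 2.25e-09 by camera and adjusted p = 0.624 with an estimated correlation. So had stellate and fibroblast genes. The stellate list had a median of 0.57, with adjusted p = 0.000683 by camera and adjusted p = 0.624 with an estimated correlation. Ribosomal protein genes moved the same way. The ribosomal protein list had a median of 0.87, with adjusted p = 6.02e-15 by camera and adjusted p = 0.624 with an estimated correlation. Genes of oxidative phosphorylation did as well. The oxidative phosphorylation list had a median of 0.50, with adjusted p = 5.72e-07 by camera and adjusted p = 0.624 with an estimated correlation. Of the members of these 4 lists 0 were called over all genes or adjusted over the list alone. These 4 calls held without each of the 8 libraries in turn. Inflammatory mediators had a more negative response (median -0.65, adjusted p = 0.00809 by camera, adjusted p = 0.624 with an estimated correlation), a call lost without wild-type BDL replicate 2 (adjusted p = 0.102), control labelled HO-1 deleted replicate 2 (0.261) or BDL labelled HO-1 deleted replicate 1 (0.253). So had cell cycle genes (median -0.53, adjusted p = 0.00411 by camera, adjusted p = 0.624 with an estimated correlation), lost without wild-type BDL replicate 2 (0.171) or control labelled HO-1 deleted replicate 2 (0.309). A more positive response was also called for endothelial genes. The endothelial list had a median of 0.26, with adjusted p = 0.00761 by camera and adjusted p = 0.624 with an estimated correlation. Lipid-associated macrophage genes followed, with 1 up adjusted over the list alone. The lipid-associated macrophage list had a median of 0.25, with adjusted p = 0.0233 by camera and adjusted p = 0.917 with an estimated correlation. Monocyte genes followed too. The monocyte list had a median of 0.40, with adjusted p = 0.045 by camera and adjusted p = 0.624 with an estimated correlation. Interferon genes were the last of the lists called. The interferon list had a median of 0.23, with adjusted p = 0.0328 by camera and adjusted p = 0.917 with an estimated correlation. Without control labelled HO-1 deleted replicate 1 or BDL labelled HO-1 deleted replicate 2 each of these 4 lost its call (adjusted p 0.0589 to 0.275 and 0.0902 to 0.94). The endothelial, lipid-associated and monocyte calls were also lost without wild-type BDL replicate 2 (0.131 to 0.552), the lipid-associated, monocyte and interferon calls without wild-type control replicate 1 (0.0764 to 0.63), and the interferon call without wild-type BDL replicate 1 (0.600).

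By edgeR, 1 gene was called and 1316 had an unadjusted p under 0.05; DESeq2 called 84. The count was 195 without the female library, wild-type BDL replicate 1, 11 without wild-type BDL replicate 2, and 0 without wild-type control replicate 2, control labelled HO-1 deleted replicate 1 or 2, or BDL labelled HO-1 deleted replicate 1. Camera called 8 lists higher and 2 lower, and fry 0. Total counts shifted the median of all genes by -0.14, gave 7 calls and turned the median of the lipid-associated macrophage list below 0.

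Averaged over treatments (4 libraries against 4), the genotype comparison asks what differs between the labelled genotypes on average, which does not show a difference in each condition. Hmox1 was higher by 1.84 ± 0.17 in the libraries labelled HO-1 deleted (adjusted p = 0.00045). Its call held without each of the 8 libraries in turn. Over 23 alternatives its log2 fold change ran from 1.05 to 1.94 and its adjusted p from 1.58e-17 to 0.402. Cacna1a was 1.70 to 2.80 CPM in the 4 wild-type libraries and 22.9 to 62.3 CPM in the 4 labelled deleted (3.87 ± 0.25, adjusted p = 2.27e-05), and Ints10, a subunit gene of the Integrator complex, was also higher (1.40 ± 0.17, adjusted p = 0.00237). Lyz2 was lower in the libraries labelled deleted (-6.03 ± 0.41, adjusted p = 3.09e-05), as were Dab1 (-4.31 ± 0.27, adjusted p = 2.27e-05), Lnx1 (-2.96 ± 0.34, adjusted p = 0.00229), with 8.13 to 18.2 CPM against 0.665 to 2.09 CPM, and Rfxank, a transcription factor gene of MHC class II (group means of 17.4 and 16.7 CPM in wild-type controls and BDL, 7.32 and 4.88 CPM in those labelled deleted, adjusted p = 0.00342). Notch1 was not called (0.02 ± 0.17, adjusted p = 0.983).

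Several of the 44 genes called lie close together. On chromosome 2, 10 called genes between 176708328 and 178034022 (build mm10), zinc-finger and predicted genes such as Zfp971, were lower. On chromosome 8, 9 called genes between 68793929 and 85386345 included Hmox1, Cacna1a, Ints10 and Rfxank in both directions, and 25 of the 44 lay outside both stretches. Within 20 Mb of Hmox1, 32 of 280 genes tested had an unadjusted p under 0.01.

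**Figure D4:**
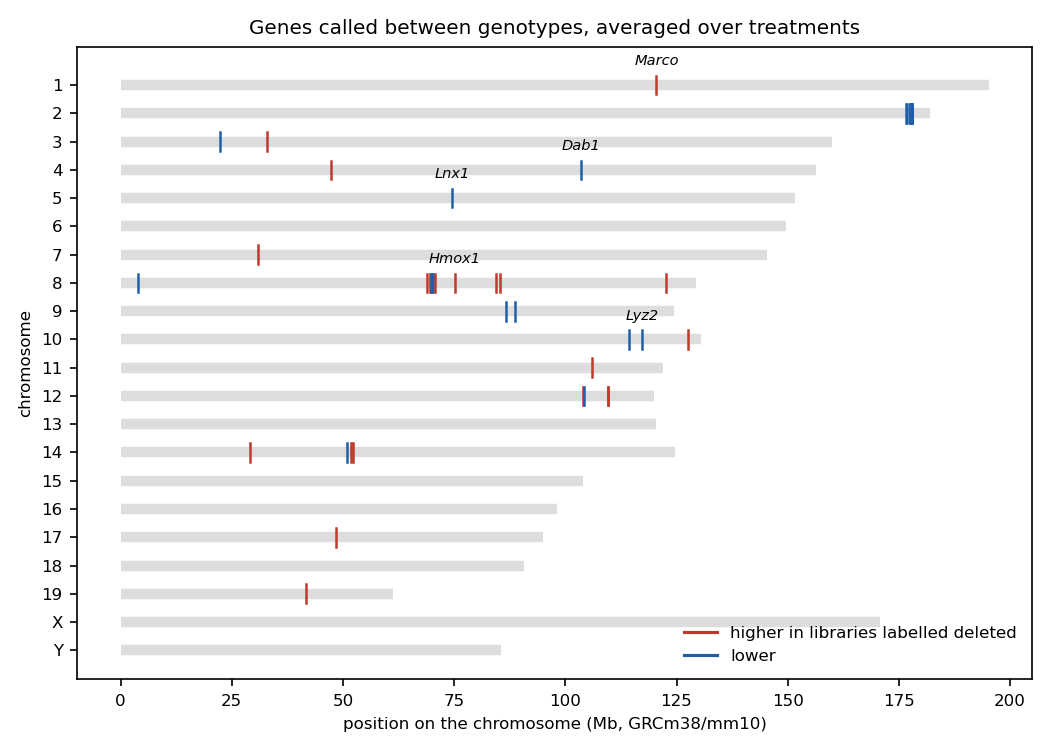
Positions of the 44 genes called in the genotype comparison averaged over treatments, in Mb along each mouse chromosome (build mm10), higher (red) or lower (blue) in the libraries labelled HO-1 deleted. Of these, 10 lie on chromosome 2 between 176708328 and 178034022 and 9 on chromosome 8 between 68793929 and 85386345.

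Acute-phase genes were higher as a list, with 1 up and 0 down (7 and 0 adjusted over the list alone). The acute phase list had a median of 0.39, with adjusted p = 3.02e-11 by camera and adjusted p = 0.445 with an estimated correlation. Matrix genes were higher with 0 members called (2 and 0 adjusted over the list alone). The matrix list had a median of 0.57, with adjusted p = 5.07e-11 by camera and adjusted p = 0.445 with an estimated correlation. Kupffer cell genes were higher, with 2 up and 0 down (3 and 0 adjusted over the list alone). The Kupffer cell list had a median of 0.35, with adjusted p = 1.00e-06 by camera and adjusted p = 0.445 with an estimated correlation. Lipid-associated macrophage genes were higher, with 1 up and 0 down (2 and 0 adjusted over the list alone). The lipid-associated macrophage list had a median of 0.42, with adjusted p = 2.39e-06 by camera and adjusted p = 0.445 with an estimated correlation. Stellate genes were higher with 0 members called either way. The stellate list had a median of 0.28, with adjusted p = 0.000986 by camera and adjusted p = 0.445 with an estimated correlation. The interferon list was lower with 0 members called (0 and 5 adjusted over the list alone). The interferon list had a median of -0.37, with adjusted p = 2.39e-06 by camera and adjusted p = 0.445 with an estimated correlation. These 6 calls held without each library in turn. Of the 6, the acute-phase and Kupffer cell lists were called in controls and after BDL. In controls the matrix (median 0.19, camera adjusted p = 0.631), stellate (0.08, 0.925) and lipid-associated macrophage lists (0.22, 0.109) were not called, and after BDL the interferon list was not (-0.20, 0.11). The heme and iron, lysosome, neutrophil, bile acid and oxidative phosphorylation lists were called too (camera adjusted p 0.000719 to 0.0280; adjusted p 0.445 to 0.677 with an estimated correlation). In controls only the last of these was called, and after BDL only the first 3. Each lost its averaged call without at least 1 library. Bile acid genes did so without wild-type control replicate 1 (0.0701), the female library (0.147) or control labelled HO-1 deleted replicate 2 (0.124). Neutrophil genes did so without wild-type control replicate 1 (0.0621) or BDL labelled HO-1 deleted replicate 2 (0.127), and heme without the latter (0.0633). The lysosome call ended without that library (0.652) or wild-type BDL replicate 2 (0.0931), and oxidative phosphorylation without wild-type control replicate 1 (0.307), the female library (0.786), or replicate 1 of control (0.163) or BDL (0.747) labelled HO-1 deleted. Hepatocyte genes had a median of 0.02, a mean of 0.03 and a downward camera direction (adjusted p = 0.854). Across genes, fold changes between genotypes in controls and after BDL correlated with Pearson r = 0.216 and Spearman rho = -0.0063, and 25 of the 27 genes called in controls had the same sign after BDL.

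By edgeR, 44 genes were called, 21 higher and 23 lower, with 1345 at an unadjusted p under 0.05; DESeq2 called 152, and lists called were 11 by camera and 0 by fry. Without wild-type control replicate 1 the count was 26, without the female library 121, without wild-type BDL replicate 2 67 and without BDL labelled HO-1 deleted replicate 1 18. Total counts shifted the median of all genes by -0.60, gave 10 higher and 78 lower, and turned every positive list median named here below 0, and the RN45S share as a covariate left 19 calls (6 higher, 13 lower).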

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

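The tests of explanations in this part were chosen after the results were seen, except the counts over all splits of the libraries into other groups.

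The result furthest from the labels is Hmox1, which was higher by 1.84 ± 0.17 in the libraries labelled HO-1 deleted. It does not refute them, since a myeloid deletion need not lower Hmox1 RNA from other cells. A wrong genotype label on 1 library was tested with genes called without the library in question and without Hmox1: 1 of 8 libraries, wild-type BDL replicate 1, lay nearer the other genotype (position 0.519 on 120 genes, where 0 is wild type and 1 deleted), so a wrong label stays a candidate explanation by that rule. A further test was added after that library came up: Hmox1 stayed higher without any 1 library, at 1.72 to 1.94 with an SE of 0.17, so a single wrong label is not the source of the difference, and Lyz2 in every wild-type library, that one included, was above every library labelled deleted (8.04 to 27.3 CPM against 0.128 to 0.665 CPM). A swap of 2 libraries between the labelled genotypes would give more calls once undone, but over the 16 splits that exchange 1 library of each label the most calls by genotype were 1, against 35 with the labels as given. A larger share of RNA from 1 cell type would raise its markers by about as much as Hmox1, but over 10 cell type lists the highest upper quartile of members was 0.935 (neutrophils) and the highest median 0.42 (dendritic cells), below 1.67, the log2 fold change of Hmox1 minus its SE. The Kupffer cell list without Hmox1 had a median of 0.34 (SD of members 0.54). A rule first set on medians plus SDs was not met by the monocyte and neutrophil lists (SDs 1.53 and 1.67), but it was a poor one, since each SD came largely from 1 member: it was 0.38 without Lyz2, the Cre locus, and 0.89 without Cebpe, which had 1 count in wild-type controls. A change in part of 1 cell type, or in a type without a list, stays open, and the Kupffer cell gene Marco was higher by 1.85 ± 0.22. A linked segment from another strain may explain it, since 8 other genotype calls lay within 20 Mb of Hmox1, against a 95th percentile of 3 in 10000 random draws (permutation p = 1e-04, the smallest these permutations can give).

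The genotype calls lay close together in the genome: 30 of 44 had another called gene within 5 Mb, against a 95th percentile of 15 in the draws (permutation p = 1e-04, the smallest these permutations can give), which is consistent with segments from another strain. Reads shared between gene copies on chromosome 2 are not the whole source, since with that stretch left out 20 of 34 called genes had another within 5 Mb, against a 95th percentile of 11 in the draws (permutation p = 1e-04, again the smallest). Within the stretch they cannot be told apart from a change in each gene: 10 of its 13 genes define it by being called lower, and of the other 3, too few to decide, 0 were higher and 1 was lower at unadjusted p under 0.05. A linked segment around Lnx1 could not be told from chance, with 7 of 134 genes within 20 Mb at unadjusted p under 0.01 and a 95th percentile of 7. Of 34 splits of 4 libraries against 4, the real one alone had as many as its 35 calls by genotype, and the highest other had 1. A complete exchange of genotype labels, Hmox1 transcripts from a recombined allele and a true rise of Hmox1 in intact cells were not tested. Nor was a difference in Cre between the lines, which lower Lyz2, its locus, leaves open in each genotype contrast.

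Hepatocyte genes fell after BDL. A smaller share of hepatocyte RNA would raise the markers of all other cells alike. The medians of the cholangiocyte and endothelial lists differed by 2.49 (SDs of members 1.39 and 0.48). BDL itself leads to bile duct growth, so this gap cannot decide whether the hepatocyte share fell, and that explanation stays open. The female library among the wild-type BDL mice was tested as a source with the 932 genes lower in wild type: in the libraries labelled HO-1 deleted, all male, 919 of them were lower and 609 were called lower, with a median of -1.04 and quartiles of -1.69 and -0.63. The same splits were run for BDL, and 1 of 34 splits, the real one, had as many as its 5085 calls, the highest other having 1.

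The response to BDL differed between the labelled genotypes for Tmc5 (-5.90) by a test of the interaction itself. By camera on the interaction it differed for lists with medians of 0.40 (monocyte), 0.25 (lipid-associated macrophage), -0.65 (inflammatory), 0.23 (interferon), 0.87 (matrix), 0.57 (stellate), 0.26 (endothelial), -0.53 (cell cycle), 0.50 (oxidative phosphorylation) and 0.87 (ribosomal protein). With an estimated correlation 0 of these lists kept the call, and the cause of these differences was not tested.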

How the results depend on the processing

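The alternatives chosen after the data were seen are named above. The cause of any change below was not tested. No paired analysis was possible, as no replicate numbers link libraries across groups. All alternatives planned were run except those that a contrast does not allow: a fit to only the 4 libraries compared for the interaction and the averaged contrasts.

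For BDL in wild type, 2607 genes were called. Alternatives gave 550 with total counts, 1315 with a test against a fold of 1.5, 387, 293 and 82 on FPKM (pseudocount 1, pseudocount 0.1 and no filter), 1477 with the RN45S share as a covariate, and 881 to 2797 without 1 library. For BDL in the libraries labelled HO-1 deleted, 3895 were called. There total counts gave 918, the test against a fold of 1.5 gave 2007, FPKM gave 452, 465 and 97, and leaving out 1 library gave 1644 to 4392. For BDL averaged over genotypes, 5539 were called, against 2008 with total counts, 2536 with the test against a fold of 1.5, 1152, 1039 and 648 on FPKM, 3616 with the RN45S share and 3913 to 5551 without 1 library. On FPKM with pseudocount 1 the median of all genes shifted by -0.59 for genotype in controls, -0.35 for genotype after BDL, 0.23 for the interaction and -0.46 for genotype averaged.

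For genotype in controls, 27 genes were called. Total counts gave 44, DESeq2 100, no filter on low counts 126, an adjusted p of 0.1 gave 48, a fit to only the 4 libraries compared 65, FPKM 77, 67 and 10, the RN45S share 10, the fit without the female and the lowest-count library 62, and leaving out 1 library 12 to 52. For genotype after BDL, 9 were called, against 95 with total counts, 171 with DESeq2, 206 with no filter, 54, 74 and 3 on FPKM, 264 without the female and the lowest-count library, and 1 to 306 without 1 library. For the interaction, 1 gene was called, against 7 with total counts, 84 with DESeq2, 138 with no filter, 0 with a mean of at least 50 counts, 56, 42 and 2 on FPKM, 0 with the RN45S share, 213 without the female and the lowest-count library, and 0 to 195 without 1 library. For genotype averaged over treatments, 44 were called, against 88 with total counts, 152 with DESeq2, 182 with no filter, 68 at an adjusted p of 0.1, 29 with the test against a fold of 1.5, 78, 79 and 10 on FPKM, 19 with the RN45S share, 146 without the female and the lowest-count library, and 18 to 121 without 1 library.

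Camera called 18 lists for BDL in wild type, 18 in the libraries labelled HO-1 deleted, 7 for genotype in controls, 13 for genotype after BDL, 10 for the interaction, 19 for BDL averaged and 11 for genotype averaged. With an estimated correlation all 7 counts were 0, and fry gave 0 for genotype in controls, genotype after BDL, the interaction and genotype averaged. The RN45S share left 6 for genotype after BDL. Without 1 library the counts were 17 to 19, 17 to 20, 7 to 12, 3 to 17, 5 to 13, 18 to 19 and 8 to 16, in the order given. The correlation of BDL responses between genotypes, 0.778, was 0.655 without the female and the lowest-count library and 0.518 to 0.768 without 1 library.

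Each of the 775 results for named genes was compared with its value under up to 24 alternatives. Of these comparisons, 16437 were the same, 980 were weaker (a call lost), 194 were stronger and 0 reversed. In 268 of those counted as the same the sign changed without a call on either side, and a further 662 had no value.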

Other observations

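The genes described in this part were picked after the results were seen, while the tests behind their values were chosen before.

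Meg3 and Rian are noncoding RNAs of the imprinted Dlk1-Dio3 locus on chromosome 12 (Meg3 from 109541001, Rian from 109603940), which in adult liver are low in hepatocytes. Both were highest in controls labelled HO-1 deleted, with Meg3 at 98.3 ± 9.85 CPM against 13.8 ± 0.749 CPM in wild-type controls and Rian at 32.1 ± 6.44 against 4.82 ± 1.63 CPM. After BDL they were at 9.001 ± 0.51 and 5.09 ± 2.07 CPM for Meg3 and 2.33 ± 0.478 and 1.06 ± 0.428 CPM for Rian, in the libraries labelled deleted and in wild type.

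Alas2, which makes the first step of heme in red cell precursors, went from 38.8 ± 4.85 to 4.52 ± 0.56 CPM after BDL in wild type (-3.11 ± 0.28, adjusted p = 7.81e-05) and from 25.7 ± 2.7 to 4.36 ± 1.67 CPM in the libraries labelled HO-1 deleted (-2.69 ± 0.29, adjusted p = 0.000155). In wild type and in the libraries labelled HO-1 deleted, Atf3, a transcription factor gene of stress, rose by 3.26 ± 0.50 (adjusted p = 0.00185) and 2.56 ± 0.50 (adjusted p = 0.00455), and Ier3, an early response gene, by 3.63 ± 0.44 (adjusted p = 0.00042) and 3.23 ± 0.42 (adjusted p = 0.000421). The list of protein folding and stress genes was not called in either genotype.

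Of Lnx1 and Notch1, which the series title names, Lnx1 differed by genotype, lower by 2.96 in the libraries labelled HO-1 deleted averaged over treatments, while Notch1 was not called. Over 23 alternatives the log2 fold change of Lnx1 ran from -3.62 to -1.46 and its adjusted p from 2.21e-15 to 0.214. The low CPM of Lnx1 (0.665 to 2.09 in the libraries labelled deleted) limits its precision.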
